A study of Homo sapiens with 4 samples.

How the data were processed

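Human epidermal keratinocytes, grown from commercial progenitors of the basal layer of the epidermis, were profiled on 4 arrays, 2 from cultures given isosorbide di-(methyl fumarate) (IDMF) and 2 from cultures given water. Per the labels' protocols, all cultures received IL-17A and IL-22 at 100 ng/ml each and TNF-alpha at 10 ng/ml for 24 h before IDMF or water was added, and RNA was taken after a further 24 h. Biotinylated cRNA was made from 6 µg of total RNA by the Affymetrix procedure, per the labels' protocols. The dye field of the labels names Cy3 instead, and the values do not settle which applies. The dose of IDMF is not given in the sources used here.

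The deposited table holds 1 value per probe set and array on a log2 scale, and RMA is named in the submitters' processing notes without a version or further settings. The values ran from 1.95 to 14.1, and the 4 array medians lay between 4.43 and 4.49. The log2 scale was therefore taken from the tool's name and the range of the values, and no further transformation or normalization was applied. RMA normally corrects the background and equalises the arrays' distributions, so a change shared by most transcripts would be hard to see in such values, and small fold changes of dim probe sets are compressed.

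Probe sets were named through the array's platform annotation. Of 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none. Of the array's 62 control probe sets, 6 had 1 symbol and 56 had none. Symbols were compared with a RefSeq gene table by Entrez identifier, which matched 41037 probe sets and changed 0 symbols. Sex-linked marker genes (59 probe sets) and the 6 control probe sets with a symbol were left out, which left 41032 probe sets for 19740 genes. Where a gene had several probe sets, as 10511 genes did, the one with the highest mean over the 4 arrays stood for it. No gene was named from a probe set with several symbols or with none.

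Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options, all 4 arrays, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over 19740 genes with a threshold of 0.05. A fold of at least 1.5 was counted as a second criterion. Fold changes are IDMF minus control in log2 units, given with the standard error of the fit. The fit had 2 residual degrees of freedom and a prior worth 3.13, which gave 5.13 in all. The number of arrays limits the precision. Nothing in the labels says that the arrays of a group came from separate cultures or donors, so p-values measure only the spread between these arrays, which may be technical. Exact permutation of 4 arrays cannot give a p below 0.333.

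Before the data were examined, 18 gene lists were written from general knowledge of keratinocytes, of the cytokines and of fumarates: targets of NRF2, genes raised by IL-17A, TNF or IL-22, NF-kB targets, interferon-stimulated genes, genes raised in psoriatic lesions, cell cycle, cornified differentiation, basal adhesion, activation and wounding, unfolded protein and integrated stress response, heat shock, sterol synthesis, glycolysis and hypoxia, p53 targets, metallothioneins, and markers of fibroblasts, melanocytes and leukocytes. Each was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 18 lists. The same lists were tested with camera at a correlation estimated from the data and with fry. On simulated arrays, camera with an estimated correlation called 0 of 10 shifted lists. A list that fails it is therefore not shown to be unchanged. Members were also adjusted over each list alone.

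The rule for named genes was fixed at the same time. It takes in each direction the 12 genes with the largest fold change past the threshold, whose IDMF arrays both lie on 1 side of both control arrays and whose brighter group lies above the median of the table (4.45). Where fewer than 12 passed, genes with the smallest p filled the places and are described as not passing. It also takes from each list the 2 higher and 2 lower members with the smallest p above that brightness, and a fixed set around KEAP1, NRF2, the receptors of the cytokines and their best known products. HCAR2 and DEFB4A of that set were not measured by a probe set with a single symbol and are not analysed here. Other genes named in the text are said to have been chosen after their values were seen.

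The gene test was tried on simulated arrays with the spread of these data and 200 changed genes among 19740, in 10 runs. With 2 arrays against 2 it recovered 85.2% of genes changed by 1 log2 unit and 98.4% of those changed by 2, with 5.10% false calls. Adjustment is stricter where fewer genes change, so recovery in data with fewer changed genes would be lower. Alternatives covered the probe set rule, a filter on dim genes, quantile normalization and median centring, the prior, a block for the replicate number, the threshold, an ordinary linear model, leaving out each array, and the other list tests.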

Results

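IDMF is a fumarate ester, and the series title presents it as a candidate for topical treatment of psoriasis. The arrays asked which transcripts differed between cytokine-stimulated keratinocytes given IDMF for 24 h and those given water (n = 2 arrays per group). Across probe sets Pearson's r was 0.997 between the control arrays, 0.997 between the IDMF arrays and 0.995 to 0.996 between arrays of different groups. Probe sets are not independent replicates, so these values describe the arrays only. The SD over genes of the log2 difference was 0.170 and 0.171 within groups and 0.235 to 0.249 between them. A few control probe sets set arrays apart. The 5′ probe set of 18S ribosomal RNA read 9.56 on control array 2 and 12.3 on each of the others. The log2 signal of the 3′ over the 5′ probe set of ACTB, a sign of RNA integrity, was 0.63 and 0.68 in controls and 0.49 on both IDMF arrays. For GAPDH it was 0.20 and 0.30 against 0.12 and 0.16.

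The genes past the threshold were few, and most were higher in IDMF. SPP1 (osteopontin, a secreted matrix phosphoprotein) and MAP2 (a microtubule-associated protein best known from neurons) were among them. The smallest change that passed was 0.86 log2 units, so smaller changes may have been missed. The count depended on the settings, with 252 genes among bright genes only and 550 with a trend and robust prior. SPP1 rose from a mean of 3.19 to 6.84, a log2 fold change of 3.65 ± 0.10 (SE, n = 2 per group, limma adjusted p = 0.00197). Its control mean is dim, under the table's median of 4.45, so the size of this fold is uncertain. MAP2 rose by 3.10 ± 0.07 (adjusted p = 0.00197). The aldo-keto reductases AKR1C3, AKR1C1 and AKR1C2 rose by 2.74, 2.38 and 2.16, the quinone reductase NQO1 by 2.36, the glutathione peroxidase GPX2 by 2.36 and the iron-binding nuclear protein PIR by 2.43. The largest fall was that of SLC6A14, an amino acid transporter, with a log2 fold change of -1.74 ± 0.13 (limma adjusted p = 0.0294).

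In all, 33 of 19740 genes passed the threshold, 28 higher and 5 lower in IDMF, and each of the 33 also passed the fold minimum of 1.5. At least 2-fold changes were seen in 27 of them, 25 up and 2 down. The pseudogene NMRAL2P rose by 2.45, the hair follicle structural protein TCHH by 1.97, the taurine transporter SLC6A6 by 1.41 and the Popeye-domain protein POPDC3 by 1.35, with limma adjusted p from 0.00466 to 0.0278. The other genes that fell were LMO7 (-1.01), the G protein-coupled receptor MRGPRX3 (-0.94), the tissue plasminogen activator PLAT (-0.91) and the sterol exporter ABCG1 (-0.88), with limma adjusted p from 0.0339 to 0.0461. Below the threshold, the log2 fold changes of the lower genes with the smallest p were -0.77 for KRT75, -1.31 for IL23A, -1.08 for EGLN3, -0.66 for MICALCL, -0.73 for MMP9, -0.71 for SPRR2C and -1.49 for CD200, with limma adjusted p from 0.0763 to 0.0915. The IDMF and control arrays did not overlap for 10122 genes, or 51.3%, where chance gives 33.3%, and 3927 genes had an unadjusted p under 0.05. The calls did not hold with any 1 of the 4 arrays left out. Such a fit leaves 1 array in a group, so the spread comes from the other group alone. The direction of the 33 genes could not change there, since the groups did not overlap for any of them. The smallest of their log2 fold changes was 0.81 in size. AKR1C1 and AKR1C2 are near-identical paralogs whose probe sets can share transcripts, so their separate values are uncertain. Another probe set of opposite sign exists for 9 of the 33 genes, SPP1, GPX2 and SLC6A6 among them. For these 3 it read -0.04, -0.17 and -0.02 (limma, unadjusted p from 0.188 to 0.824), little change rather than a fall. With the mean of a gene's probe sets the log2 fold change was 1.81 for SPP1, 1.42 for AKR1C1 and 1.09 for GPX2, and SLC6A6 (0.48) and LMO7 (-0.35) did not pass. As with SPP1, 1 group mean lies under the table's median for TCHH, AKR1B10, CCNE2, EGLN3, GDF15 and PDGFRB, and both do for TNFRSF1B and TNIP3, so the sizes of their folds are uncertain.

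**Figure D1:**
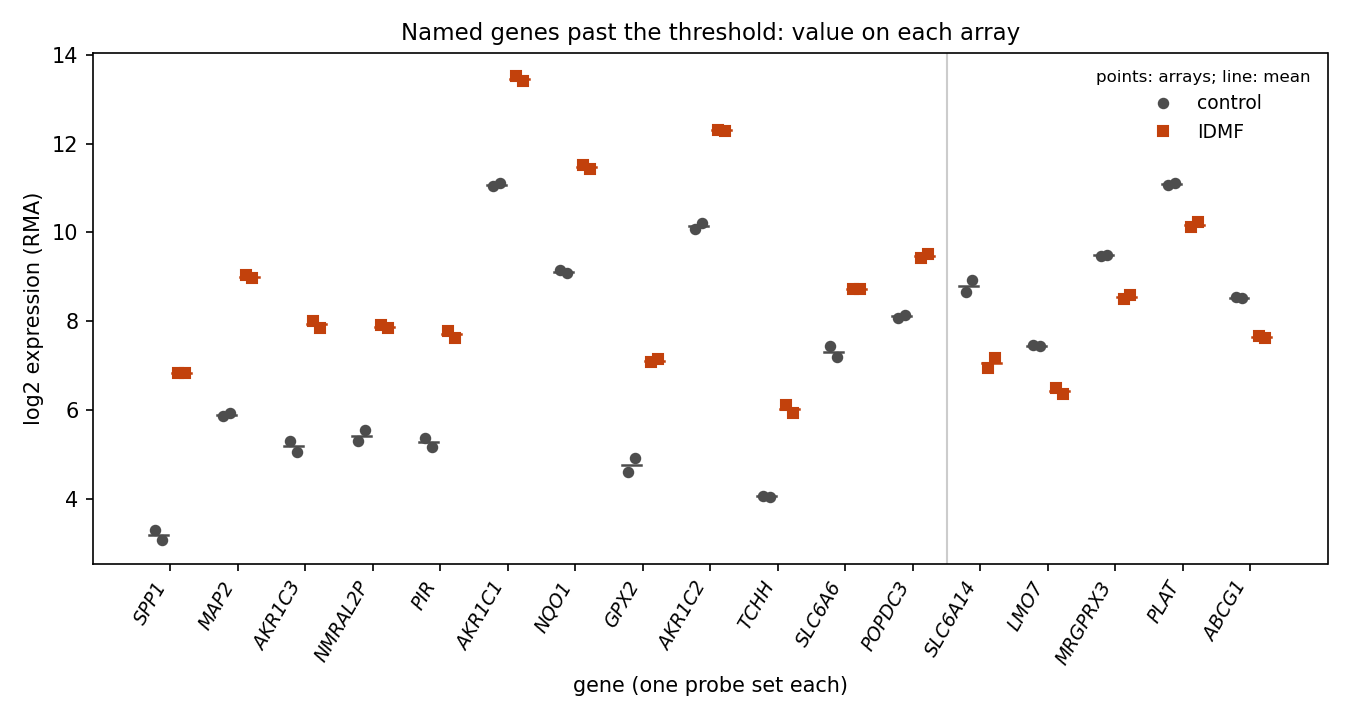
Log2 expression (vertical axis) of the named genes past the threshold (horizontal axis) on each control and IDMF array, with points for arrays and short lines for group means of n = 2. For each gene both IDMF arrays lie on the same side of both control arrays, above them for the 12 genes left of the vertical line and below them for the 5 on the right.

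Targets of NRF2, the transcription factor that drives antioxidant and detoxifying enzymes, rose as a group. The median log2 fold change of 32 measured members was 0.67, and 30 were higher in IDMF (camera, limma, adjusted p = 1.86e-21; adjusted p = 0.141 with an estimated correlation). Over all genes 10 members rose and 0 fell, and adjusted over the list alone 23 rose, 0 fell and 9 did not pass. Beside the AKR1C genes, NQO1, PIR and GPX2, those 10 hold the cystine transporter SLC7A11 (1.29), the pentose phosphate enzyme PGD (1.10), glutathione reductase GSR (1.08) and carbonyl reductase CBR1 (0.87), named after their values were seen. The genes that rose overlapped the list more than chance gives, with 10 shared where 0.0454 would be (one-sided Fisher's exact p = 3.37e-22).

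HMOX1, heme oxygenase and a widely used NRF2 target, had a log2 fold change of -0.02 ± 0.13 (95% interval -0.37 to 0.32, limma adjusted p = 0.946). TRIM16L, the other member that was lower, read -0.25 (adjusted p = 0.286). The values were 0.29 for KEAP1, which holds NRF2 in check, and -0.17 for NFE2L2, which encodes NRF2, with limma adjusted p of 0.147 and 0.293. HCAR3, a hydroxycarboxylic acid receptor, read -0.73 (adjusted p = 0.0996).

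Genes that keratinocytes raise in response to IL-17A, TNF or IL-22 were lower in IDMF as a group, although 0 passed over all genes. All cultures received the cytokines. The arrays therefore cannot tell a lower response to them from a lower level that the genes would have without them. The median log2 fold change of 31 measured members was -0.41, with 27 lower (camera, limma, adjusted p = 4.76e-13; adjusted p = 0.409 with an estimated correlation). With every probe set on its own the median was -0.25. The estimated correlation between members was 0.33, against the preset of 0.01. Adjusted over the list alone, 22 fell, 2 rose and 7 did not pass. IL23A, a subunit of interleukin 23, fell by 1.31 ± 0.15, and the epidermal cytokine IL36G fell by 0.86 ± 0.11 (limma, adjusted p = 0.00395 for both, adjusted over the list alone). The antimicrobial protein S100A7 (-0.64) and the chemokines CCL20 (-0.51) and CXCL8 (-0.25) also fell when adjusted over the list alone. The 2 that rose were the tryptophan-degrading enzyme KYNU (0.46) and, named after its value was seen, TNIP3, which is dim in both groups. CXCL3 read 0.03. The 3′ over 5′ signals of ACTB and GAPDH were lower on the IDMF arrays, by log2 differences of -0.16 and -0.11. This holds beside every list described here, since it separates the same groups of arrays.

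**Figure D2:**
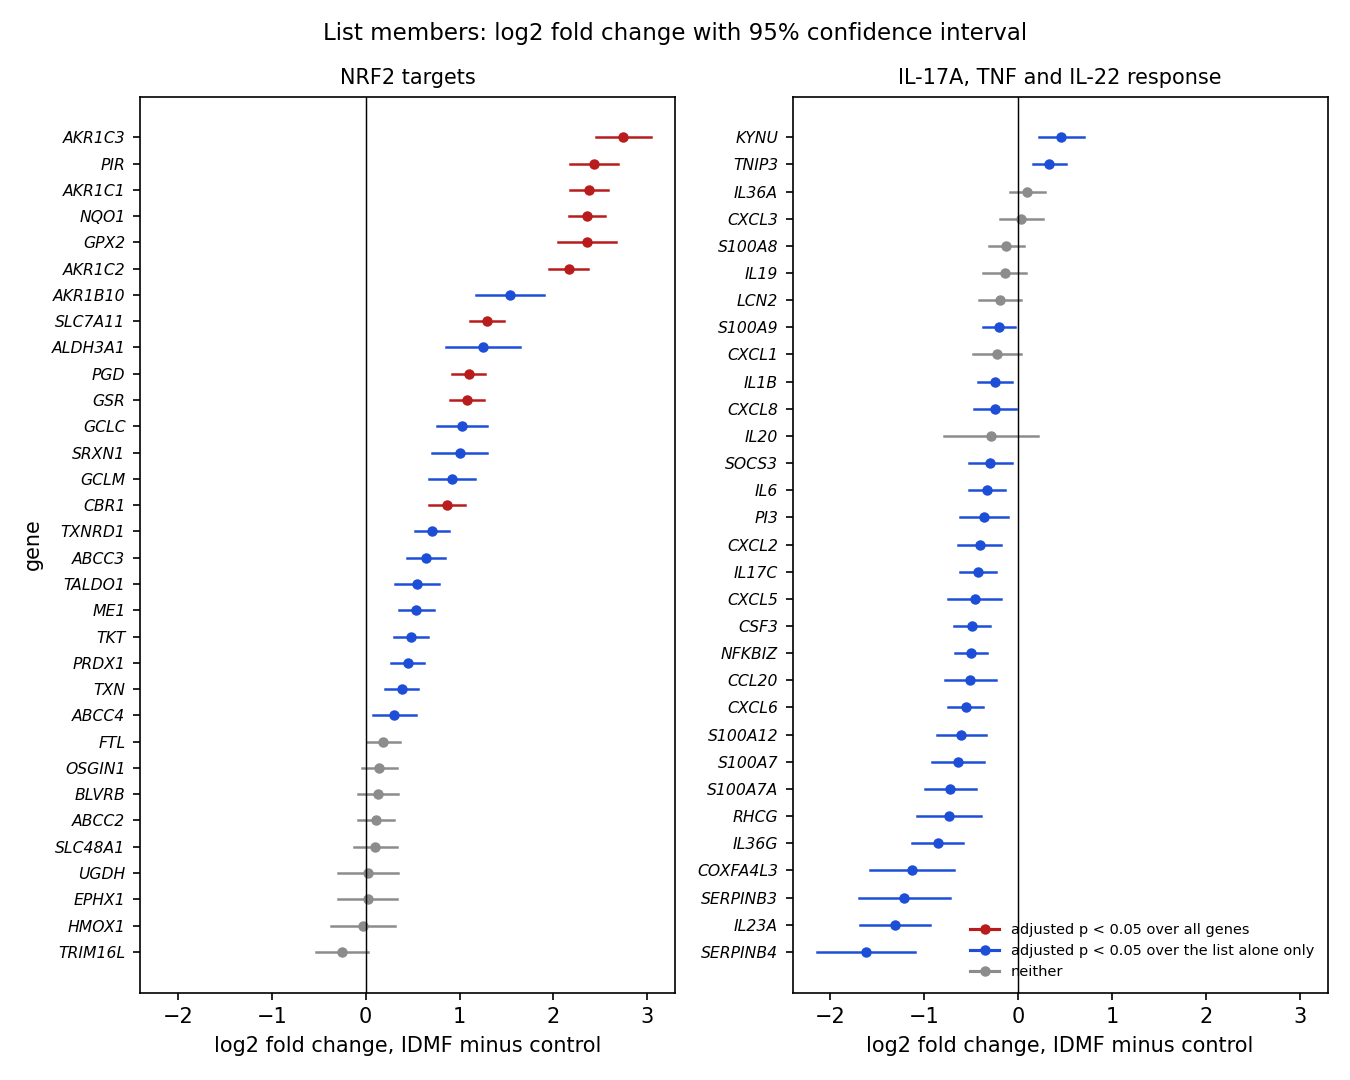
Log2 fold change, IDMF minus control (horizontal axis), with its 95% confidence interval from limma (n = 2 per group) for each measured NRF2 target and each measured member of the cytokine response list (vertical axis). Of the NRF2 targets 30 lie above 0 and of the cytokine response genes 27 lie below 0. Red marks genes past the threshold over all genes, blue those past it over the list alone, grey the others.

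The receptors for these cytokines gave log2 fold changes of -0.04 for IL17RA, -0.21 for IL17RC, -0.16 for IL22RA1, -0.06 for TNFRSF1A and -0.14 for TNFRSF1B, with limma adjusted p from 0.312 to 0.804. NF-kB targets went both ways, with a median of -0.04 over 21 members (camera, limma, adjusted p = 0.336). Adjusted over the list alone, the dendritic cell marker CD83 rose by 0.73, the adhesion molecule ICAM1 fell by 1.17 and 19 did not pass, and over all genes 0 passed. NFKBIE read 0.23 and TNFAIP2 read -0.57. The mean of this list and camera point down, while fry points up, and the median was 0.01 with median centring.

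Interferon-stimulated genes were also lower, with a median of -0.49 over 29 measured members and 28 of them lower (camera, limma, adjusted p = 8.52e-12; adjusted p = 0.409 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 18 fell, 0 rose and 11 did not pass. The antiviral GTPase MX2 fell by 1.28 ± 0.16 and the oligoadenylate synthetase OAS2 by 0.76 ± 0.12 (limma, adjusted p = 0.0141 and 0.0148, adjusted over the list alone). The list's mean per array differed by 0.231 between the IDMF arrays, more than the smallest gap between the groups, 0.216. The estimated correlation between its members was 0.54, against the preset of 0.01.

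Genes known to be raised in psoriatic lesions had a median of -0.21 over 33 members, with 26 lower (camera, limma, adjusted p = 5.44e-06; adjusted p = 0.409 with an estimated correlation). Of these, 14 also belong to the cytokine response list, so the lists are not independent. Adjusted over the list alone 10 fell, 3 rose and 20 did not pass, and over all genes 0 passed. The list's mean per array differed by up to 0.186 within a group, more than the smallest gap between the groups, 0.145. The serpin SERPINB4 fell by 1.62 ± 0.20. The 3 that rose were the NRF2 target AKR1B10 (1.54, dim in controls), the secreted signal WNT5A (0.64) and KYNU.

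Late differentiation genes were lower by less, with a median of -0.14 over 32 members (camera, limma, adjusted p = 0.00124; adjusted p = 0.409 with an estimated correlation). The gap in the list's mean per array was up to 0.117 within a group and at least 0.0972 between groups, and without control array 2 the median was -0.10. Adjusted over the list alone 7 fell, 0 rose and 25 did not pass, and over all genes 0 passed. The cross-linking enzyme TGM1 fell by 0.90 and the lipid transporter ABCA12 by 0.49, while KRT10 read 0.23 and ELOVL4 read 0.13. Genes of the basal layer and its adhesions did not pass as a list (median -0.06 over 16, camera, limma, adjusted p = 0.121), and 0 members passed over all genes or adjusted over the list alone. Among bright genes only it did (adjusted p = 0.0316, lower), and the median ranged from -0.09 without control array 1 to -0.01 with median centring. There COL7A1 read 0.27, KRT5 read 0.05, ITGA2 read -0.30 and ASS1 read -0.18. The activation and wound list did not pass either (median -0.06 over 15, adjusted p = 0.120). It passed, lower, with every probe set on its own (0.0456), among bright genes only (0.0316) and with a trend and robust prior (0.0241), while its median was -0.01 with median centring. Adjusted over the list alone, 1 member rose, the matrix metalloproteinase MMP3 (0.90), and 4 fell, among them MMP9 (-0.73) and tenascin TNC (-0.57), while 10 did not pass, CCN2 (0.22) among them, and over all genes 0 passed.

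Glycolysis and hypoxia genes were lower, with a median of -0.20 over 20 members and 18 of them lower (camera, limma, adjusted p = 7.82e-07; adjusted p = 0.409 with an estimated correlation). None (0) passed over all genes, while adjusted over the list alone 5 fell, 0 rose and 15 did not pass. The oxygen-sensing hydroxylase EGLN3 fell by 1.08 and the collagen hydroxylase subunit P4HA1 by 0.48, while the glycolytic enzymes ENO1 and GAPDH read 0.06 and 0.01.

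Cell cycle genes were slightly higher, with a median of 0.15 over 34 members (camera, limma, adjusted p = 0.0169; adjusted p = 0.482 with an estimated correlation). There were 0 calls over all genes, and adjusted over the list alone 4 rose, 0 fell and 30 did not pass. The cyclin CCNE2 rose by 0.74 and the replication helicase subunit MCM6 by 0.72, while PLK1 read -0.25 and E2F1 read -0.19. The mean per array of this list differed by up to 0.182 within a group against a smallest gap of 0.0198 between groups, and the median was 0.25 without control array 1 and 0.03 without control array 2. The p53 targets had a median of 0.15 over 18 members (camera, limma, adjusted p = 0.0252; adjusted p = 0.409 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. GDF15 read 0.38, ZMAT3 0.27, PHLDA3 -0.13 and CDKN1A -0.12. Neither call held without control array 2 (camera, limma, adjusted p = 0.834 for cell cycle and 0.197 for p53 targets) or without IDMF array 2 (0.0801 and 0.0760), and the median of the p53 targets was 0.09 without control array 2. With quantile normalization the adjusted p was 0.0996 (median 0.08) and 0.0959 (median 0.10), and among bright genes only 0.200 and 0.172. With every probe set on its own the medians were 0.07 for both, and the cell cycle call was lost (adjusted p = 0.0896).

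The remaining stress and metabolic lists did not pass in the fit to all genes. The unfolded protein and integrated stress list had a median of 0.03 and a mean of -0.02 over 24 members (camera, limma, adjusted p = 0.488, direction down). Adjusted over that list alone the amino acid transporter subunit SLC3A2 rose by 0.33, the glutathione-degrading enzyme CHAC1 fell by 0.47, the stress-induced factor ATF3 fell by 0.34 and 21 did not pass, ASNS (0.27) among them. Heat shock genes had a median of 0.07 over 15 (adjusted p = 0.160), with DNAJB1 at 0.18, STIP1 at 0.20, HSPA4L at -0.12 and HSPB1 at -0.06. Sterol synthesis genes had a median of -0.04 over 18 (adjusted p = 0.0631), with EBP at 0.13, NSDHL at 0.07, STARD4 at -0.23 and INSIG1 at -0.22. The sterol list passed, lower, among bright genes only (0.00977), with quantile normalization (0.0153) and with a trend and robust prior (0.00821), while its median was 0.01 with median centring. Metallothioneins had a median of -0.04 over 8 (adjusted p = 0.599), with SLC30A1 at 0.22, MT1G at -0.07 and MT1F at -0.05. Other settings moved these small medians both ways: without IDMF array 2 the stress list read -0.02 and heat shock 0.05, and with median centring they read 0.07 and 0.12, and metallothioneins 0.00. In these 4 lists 0 members passed over all genes, and in the last 3 of them 0 passed adjusted over the list alone.

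Markers of other cell types in skin did not pass as lists (camera, limma). Fibroblast markers had a median of -0.17 over 12 (adjusted p = 0.120), with THY1 at 0.16, COL1A1 at -0.30 and PDGFRB at -0.21. Melanocyte markers had a median of -0.16 over 7 (adjusted p = 0.120), with MITF at 0.14 and PMEL at -0.16, and adjusted over the list alone SOX10 fell by 0.40. The result hung on the IDMF arrays, with a median of -0.26 without IDMF array 1, which passed (camera, limma, adjusted p = 0.0169), and of -0.06 without IDMF array 2 (adjusted p = 0.568). Leukocyte markers had a median of -0.07 over 11 (adjusted p = 0.121), with LAPTM5 at 0.17, CD3D at -0.12 and CORO1A at -0.07, and the median was -0.12 without control array 1 and 0.00 without control array 2. Over all genes 0 of these markers passed, and adjusted over the list alone 0 of the fibroblast and leukocyte markers did.

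Of the 18 lists, 8 passed with camera at the preset correlation, 3 higher and 5 lower in IDMF. With an estimated correlation 0 passed (limma, 1 at an unadjusted p under 0.05), and with fry 1 did (6 at an unadjusted p under 0.05), the NRF2 targets (adjusted p = 0.0111). In simulation, camera with an estimated correlation called 0 of 10 lists shifted by 0.4, so failing it says little about a list. The estimated correlation was 0.33 for cytokine response, 0.54 for interferon-stimulated and 0.24 for psoriatic lesion genes. For late differentiation it was 0.16, for glycolysis and hypoxia 0.22 and for cell cycle 0.24. If members correlate to that extent, camera p-values at the preset of 0.01 are too small. For the NRF2 targets it was -0.002 and for the p53 targets -0.02. Their camera adjusted p with an estimated correlation was still 0.141 and 0.409, so correlation between members does not account for the loss of those 2 calls. A correlation estimated from 4 arrays is itself uncertain.

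**Figure D3:**
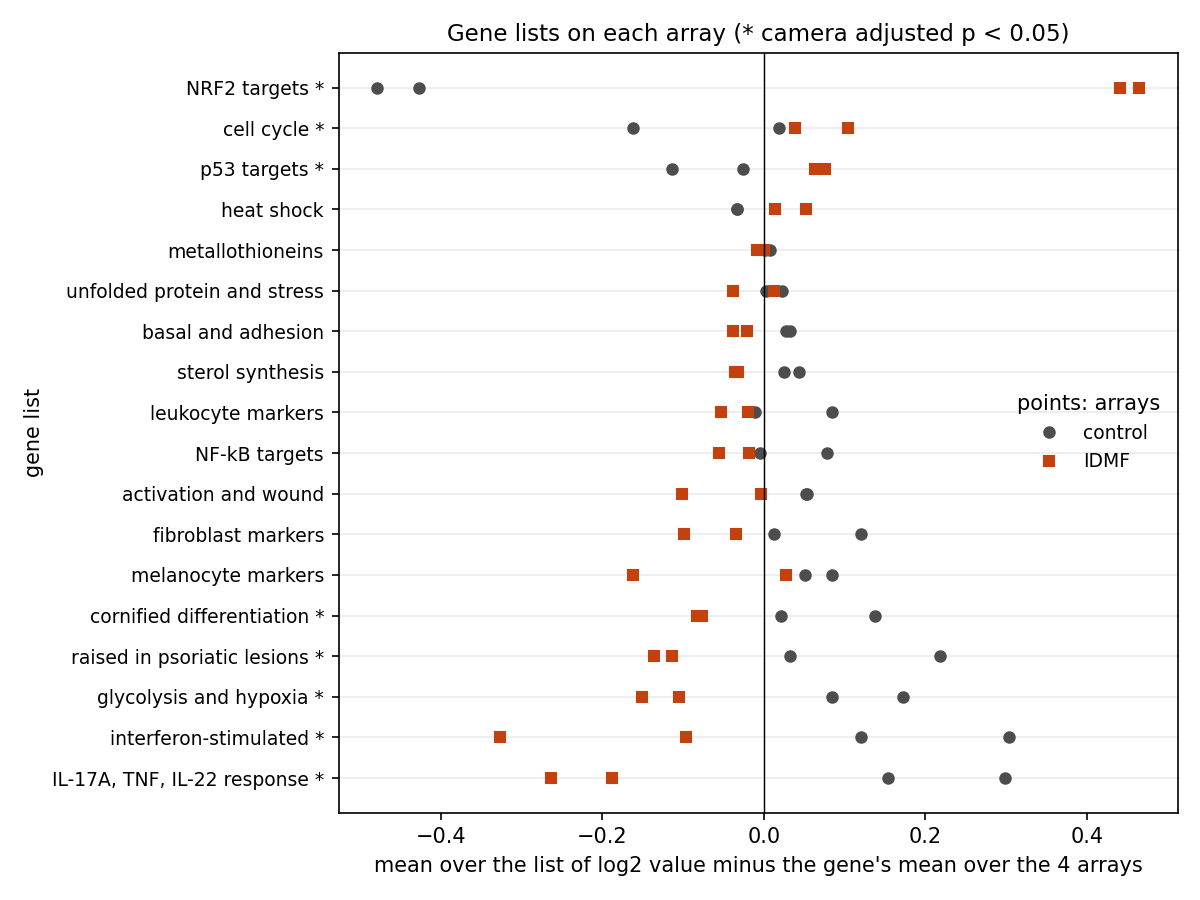
Mean over each gene list of the log2 value minus the gene's own mean over the 4 arrays (horizontal axis), for the 18 lists (vertical axis), with 1 point per control or IDMF array and an asterisk for lists past the threshold with camera. The NRF2 targets read -0.48 and -0.43 in controls against 0.44 and 0.47 in IDMF, and the cytokine response list 0.15 and 0.30 against -0.26 and -0.19.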

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

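The tests in this part were chosen after the results were seen, except the comparison of HMOX1 with its other probe sets and the comparison of SPP1, MAP2, POSTN, CCDC80 and PHEX as 1 group with theirs.

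Probe sets without a single gene symbol took no part in the gene tests, and 2 of them passed when the 54675 probe sets were tested together. Probe set 1562102_at, with no symbol, was higher in IDMF by 4.28 log2 units (4.54 and 4.43 in controls, 8.67 and 8.86 in IDMF, limma adjusted p = 0.00390). Probe set 1555854_at, with several symbols, was higher by 3.78 (5.72 and 5.79 against 9.43 and 9.63, limma adjusted p = 0.00390).

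The cytokine response and interferon-stimulated lists were both lower in IDMF. The cytokine response list separated the groups by 2.36 times its largest difference between arrays of a group. For the interferon list that ratio was 0.938. With 2 arrays a group such a ratio says little about the swing between arrays, and it was chosen after both shifts were seen. The cytokine response list also did not pass with fry (adjusted p = 0.104). The swing between arrays therefore stays open as a cause for both lists. The 3′ over 5′ signals of ACTB and GAPDH, a sign of RNA integrity, were also lower on the IDMF arrays. For GAPDH the groups lay close, at 0.20 and 0.30 in controls against 0.12 and 0.16. The relation within groups to the 3′ over 5′ signal predicts -0.277 (95% interval -1.08 to 0.53) of the cytokine list's mean of -0.45. For the interferon list it predicts 0.412 (-3.52 to 4.35), opposite in sign to the list's mean of -0.42. With 2 arrays a group these intervals rest on 1 degree of freedom and hold 0 and the whole shift, so RNA integrity stays open for both lists and cannot be told apart from treatment.

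HMOX1 stayed at -0.02 while 10 other NRF2 targets rose. Whether its probe set reports the transcript cannot be settled, because HMOX1 has only 1 probe set with a single symbol. A response of HMOX1 that had passed by 24 h was not tested, as there is no earlier time.

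SPP1, MAP2, POSTN, CCDC80 and PHEX rose, the last 3 by 0.87, 1.12 and 1.35, and were picked out after their values were seen; SPP1 and PHEX are dim in controls. A larger share of fibroblasts could bring matrix genes, but the 12 fibroblast markers had a median of -0.167 and a highest value of 0.29. The 7 bright ones had a median of -0.21 and a highest value of 0.16, which argues against a larger share. The median was -0.09 without IDMF array 1 and -0.06 with every probe set on its own. These draw on the same arrays and markers and are not separate evidence. A single deviant probe set per gene could also give such rises: for the 5 genes together the test set beforehand asked for at least 3 other bright probe sets, and with only 2, both higher, it stays open. Splitting the genes after that result was seen, MAP2 and CCDC80 each have another bright probe set that was higher, by 1.86 ± 0.27 and 0.46 ± 0.15 (2 of 2 genes), which argues against it as the whole source for them, although the size of CCDC80's rise stays open. For SPP1, POSTN and PHEX 0 bright other probe sets exist, so it stays open: among the dim ones, SPP1's read -0.04, PHEX's -0.05 and POSTN's -0.13, 0.10 and 0.44.

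The 4 arrays can be split into pairs in 3 ways, of which 1, the real one, gave 33 genes and the others at most 0. With 3 splits the share cannot fall under 0.05.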

How the results depend on the processing

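Testing all probe sets together and the NRF2 list without AKR1C1, AKR1C2 and AKR1C3 were chosen after seeing the data. The 33 genes past the threshold kept their sign under every alternative run gene by gene. With every probe set on its own this follows the probe set already chosen, while 9 of the 33 genes have another one of opposite sign. With an array left out the sign could not change, since the groups did not overlap for any of the 33. The number of genes that passed was 32 (31 up, 1 down) with every probe set on its own, of which 23 were among the 33, and 32 (26 up, 6 down) with the mean of a gene's probe sets, of which 25 were. With that mean 11 folds moved by over 1.5 times, the smallest to 0.31: those of SPP1, AKR1C1, GPX2, PGD, SLC6A6, POSTN, CCDC80, PHEX, GSEC, SAMD5 and LMO7. It was 35 (29 up, 6 down) with quantile normalization, 45 (40 up, 5 down) with median centring and 22 (22 up, 0 down) with all probe sets together. It was 252 (189 up, 63 down) among bright genes only, 550 (383 up, 167 down) with a trend and robust prior, 95 at an adjusted p under 0.10 and 1 with an ordinary linear model. With the 1.5-fold minimum it was 135 among bright genes and 196 with the trend and robust prior. Fewer tests account for part of the count among bright genes by construction, and for the other changes the cause was not tested. With the replicate number as a block 5 genes passed (5 up, 0 down), with or without the fold minimum. The 5 genes that fell thus all lost their call there, and 4 of them lost it with every probe set on its own. Arrays of the same number deviated from their group means with r = -0.06 across genes in 2 pairs, which gives no sign of pairing but cannot exclude it, and the labels do not say whether numbers pair arrays. Leaving out each array in turn gave 0 to 0 genes, with or without the fold minimum, at smallest limma adjusted p of 0.191 (without control 1), 0.204 (without control 2), 0.327 (without IDMF 1) and 0.278 (without IDMF 2). In these fits 2347 to 2799 genes had an unadjusted p under 0.05. Simulated arrays of those sizes recovered 49.1% (1 control array) and 27% (1 IDMF array) of genes changed by 1 log2 unit, and 96.5% and 95% of those changed by 2. As 24 of the 33 genes changed by under 2, the simulation leaves room for lost power among them, but the 9 others lost their call as well, which it does not account for. The prior was worth 2.28 to 2.30 degrees of freedom in these fits against 3.13 with all arrays, and the cause was not tested.

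The lists past the threshold numbered 8, and 6 to 10 under all alternatives but an estimated correlation (0) and fry (1). The NRF2 targets (median 0.67) had an adjusted p of 0.141 with an estimated correlation, and a median of 0.54 (adjusted p = 2.27e-17) without AKR1C1, AKR1C2 and AKR1C3. The cytokine response list (median -0.41) had adjusted p of 0.409 with an estimated correlation and 0.104 with fry, and its median was -0.25 (8.34e-10) with every probe set on its own. Of 10 simulated lists of 30 genes shifted by 0.4, camera found 10, fry 8 and an estimated correlation 0. The last had little power there, but correlated genes were not simulated. Of 863 alternative values of 95 named genes, 751 kept their side of the threshold, 54 lost it, 58 gained it and 0 called genes reversed. Of 206 values of the 16 other lists, 176 kept it, 21 lost it and 9 gained it. Fibroblast markers passed, lower, with every probe set on its own (camera adjusted p = 0.0175). Dim probe sets limit small folds, since compressed signals near background hide change.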

Other observations

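The tests and gene groups in this part were all chosen after the values were seen.

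Outside the fixed lists, 23 genes passed the threshold, 18 higher and 5 lower in IDMF. PTGR1, which reduces enones and prostaglandins, rose by 1.15, the fatty aldehyde dehydrogenase ALDH3A2 by 1.08 and the lysosomal galactosidase GLA by 1.17 (limma adjusted p = 0.0175, 0.0278 and 0.0144). Of 376 measured solute carriers, 4 passed the threshold. SLC6A6, SLC7A11 and the organic cation exporter SLC47A1 (1.05, dim in controls) rose, and SLC6A14 fell by 1.74. The magnesium-handling protein CNNM4 rose by 1.07, and the matrix-associated POSTN and CCDC80 by 0.87 and 1.12.

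Within the cell cycle list, genes of S phase and replication licensing had a median log2 fold change of 0.33, with 12 of 15 higher, and genes of mitosis 0.06, with 13 of 19 higher. Camera in limma gave an unadjusted p of 8.95e-05 for the first group (0.0527 with an estimated correlation) and 0.662 for the second. As a hypothesis, S phase genes may have moved apart from mitosis genes in IDMF. The difference between their means per array read -0.24 and -0.06 in controls and 0.14 and 0.15 in IDMF, a gap 1.12 times the largest difference within a group, which leaves it open.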
